A study of Mus musculus with 70 samples.

How the data were processed

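Poly(A) RNA was sequenced from total mouse liver and from liver resident macrophages sorted as F4/80high CD11blow, after 24 weeks on a control diet or a NASH (nonalcoholic steatohepatitis) diet. Per the labels' protocols, liver RNA was isolated with an illustra RNAspin kit, macrophage RNA with a Qiagen miRNeasy micro kit, and libraries were made with the Illumina TruSeq Stranded mRNA kit. Mice carried Lyz2.Cre+/+ alone (called WT here, the name in the sample titles) or OpnKI Mye (called KI here), by its name a knock-in of osteopontin, the product of Spp1, in myeloid cells. The 70 libraries make 16 groups of tissue, sex, genotype and diet, with 4 libraries each except the NASH groups of macrophages, with 5 each in males and 6 each in females.

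The authors deposited 3 tables of raw counts per gene symbol, whole numbers that differ in total between libraries: female liver (24982 genes), macrophages of both sexes (24982 genes) and male liver (23839 genes), with 23732 symbols in common. Per the submitters' processing notes the genome build was mm10. The aligner, the counting program, the annotation and the strand setting are not given in the sources used here, so reads of paralogs, overlapping genes and antisense genes may be split between symbols, and such genes are uncertain. The constant-region genes Ighm, Igkc, Ighd, Trac and Trbc2 and all mitochondrially encoded genes are absent from the tables, and Ly6g is absent from the male liver table.

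Before any comparison, Spp1 was read in every library, the sex genes Xist, Ddx3y, Eif2s3y, Kdm5d and Uty were compared with the sex label, and every pair of libraries within a group was checked for shared counts. The male liver WT control replicates 3 and 4 were taken as 1 library in 2 versions, since among genes with a summed count of 20 to 200 their counts differed by less than counting noise allows, and only 1 gene was higher in replicate 3 against 12671 in replicate 4. In abundant genes the versions do differ beyond noise: replicate 3 has a median of 88% of the counts of replicate 4 where that has 10 to 100, and 35.93% (11.69 to 58.45%) in the 15 genes from 100000. The mean of both was used, so that this group has n = 3 and its abundant hepatocyte genes lie between 2 unlike values. Libraries with contradicting sex genes stayed in their labelled groups and are named as labelled; each count was repeated without them.

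Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling, genes kept by filterByExpr over the groups (min.count 10, min.total.count 15), a quasi-likelihood fit with 1 mean per group, and Benjamini-Hochberg adjustment over the genes tested with a threshold of 0.05. Adjusted p values in the text come from this test unless another is named. Each tissue and sex was fitted with its 4 groups, in which NASH was compared with control diet in WT and in KI, KI with WT on each diet, and the diet effect in KI with that in WT (the interaction). Fits of both sexes of a tissue, on the genes present in both tables, gave the KI effect on the NASH diet averaged over sexes and the female minus male difference of the diet effect in WT and of the KI effect on the NASH diet. These are 26 comparisons. Spp1 per library is given as CPM over the library's total count, and all other CPM are TMM-scaled, with the mean and SD over libraries. Log2 fold changes are those of the edgeR fit. Where a group had no or almost no counts, the fitted fold change depends on the prior count and the CPM are given instead.

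Of the 33 gene lists written before the data were examined, 32 had genes in the tables. The cell type lists were resident Kupffer cell, lipid-associated macrophage, recruited monocyte, neutrophil, T and NK cell, B and plasma cell, dendritic cell, liver sinusoidal endothelial cell, hepatic stellate cell, cholangiocyte, hepatocyte and erythroid. The others were extracellular matrix and fibrosis, mitochondrial fatty acid oxidation, PPARA target, fatty acid synthesis, cholesterol synthesis and uptake, bile acid synthesis and sterol transport, lipid droplet, inflammatory cytokine and NF-kB target, acute phase and STAT3 target, oncostatin M pathway, interferon response, cell cycle, unfolded protein response, NRF2 and glutathione, arginine and urea cycle, oxidative phosphorylation, alternative activation and efferocytosis, MHC class II presentation, lysosome, and immediate early and heat shock. Each was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 3, with a preset correlation between genes of 0.01 and again with an estimated one, two-sided, adjusted over the lists of a comparison. Lists with fewer than 5 tested members were not tested. Beside the members past the adjusted p over all genes, the number past it when adjusted over the list alone is given. Lists share members in part (Arg1, Stat3, Plin2 and Cd36, among others).

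Genes were named by a rule set before the data were seen, as were the comparisons and some tests. In each comparison it takes 9 genes of prior interest (Spp1, Osm, Osmr, Arg2, Stat3, Socs3, Cpt1a, Lyz2, Cd44), then the largest rises and falls among genes past the threshold with a mean of at least 2 CPM in the higher group and, outside interactions and sex differences, no overlap between the groups. The numbers taken are 6 rises and 4 falls for the diet effect in WT, 5 and 5 for KI against WT on the NASH diet (3 and 3 averaged over sexes) and 3 and 3 for the other comparisons, and where no gene passes the 2 with the smallest unadjusted p. Last come up to 4 members of each list described with the smallest adjusted p. Unnamed gene models and sex genes were left out, and the diet effect in KI is described by counts, lists and the genes named for WT. A few genes that the rule takes are not reported here, though they remain in the counts and lists.

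Total counts per library were from 11245097 to 29966174 in male liver, from 17917827 to 23669846 in female liver, from 16512356 to 24317721 in male macrophages and from 17151791 to 26244679 in female macrophages, with 14426 to 16212 genes detected per library. The pipeline was tested on simulated counts drawn from the means and library sizes of KI and WT on the NASH diet, with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 63 of the 2-fold changes in male liver, 63 in female liver, 74 in male macrophages and 76 in female macrophages, and 88, 90, 88 and 90 of the 4-fold changes. Unchanged genes called numbered 11, 7, 3 and 9, among 12874, 13199, 12912 and 12710 genes, and 32, 27, 26 and 28 with DESeq2.

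Alternatives chosen before the data were examined were DESeq2 size factors in the same edgeR fit, no filter on low counts, DESeq2 1.42.0 in place of edgeR (all genes with a count, with its own filtering), the replicate number as a block, the mean of the hepatocyte list as a covariate in macrophages, and leaving out each library in turn. Those added after seeing the data were both versions of the duplicated library as separate libraries, its fuller version alone, leaving out the libraries with contradicting sex genes, and Lyz2 as a covariate in macrophages. Other splits of the libraries were refitted, at most 100 per comparison with a fixed seed. Gene positions and exonic lengths came from GENCODE mouse release M21, which is annotated on mm10.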

Results

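The series asks how osteopontin made by myeloid cells acts on the liver in steatohepatitis. It holds 70 RNA-seq libraries from mice kept for 24 weeks on a control or a NASH diet: 16 of total liver from males, 16 of total liver from females, 18 of sorted liver resident macrophages from males and 20 from females. WT stands for Lyz2.Cre alone and KI for the myeloid knock-in. Groups have 4 libraries each, except macrophage NASH (5 each in males, 6 in females) and male liver WT control, where 2 of the 4 are versions of 1. Total counts per library in male liver were 11245097 to 20178500 in WT control, 17445588 to 24130811 in WT NASH, 18743646 to 20749401 in KI control and 19161896 to 29966174 in KI NASH. In female liver they were 20917438 to 21849341, 18573961 to 23669846, 19987338 to 21871494 and 17917827 to 20362747 in the same order. In male macrophages they were 19064148 to 23239746, 17007445 to 24317721, 16512356 to 22247674 and 18314940 to 21808178, and in female macrophages 17151791 to 26244679, 18485924 to 23722522, 19539655 to 24801545 and 19389282 to 21659744. The first principal component carried 40.6% of the variance in male liver, 27.1% in female liver, 51.7% in male macrophages and 37.7% in female macrophages.

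Spp1, the gene knocked in, was read first in every library. In macrophages of control mice it lay at 0.268 to 0.516 CPM in male WT against 7.12 to 11.3 CPM in male KI, and at 0 to 0.199 CPM in female WT against 1.43 to 2.47 CPM in female KI, so that every KI library lay above every WT library. On the NASH diet macrophage Spp1 was 5.72 to 55.9 CPM in male WT and 43.7 to 199 CPM in male KI, and 1.15 to 11.1 CPM in female WT and 2.17 to 102 CPM in female KI. In total liver on the NASH diet every male KI library lay below every male WT library, at 22.2 to 65.8 CPM against 133 to 698 CPM, and the female groups overlapped, at 26.6 to 58.0 CPM in KI and 53.4 to 92.8 CPM in WT. Liver of control mice had 22.1 to 35.1 CPM in male WT, 14.1 to 27.8 CPM in male KI, 22.5 to 32.0 CPM in female WT and 18.1 to 40.8 CPM in female KI.

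**Figure D1:**
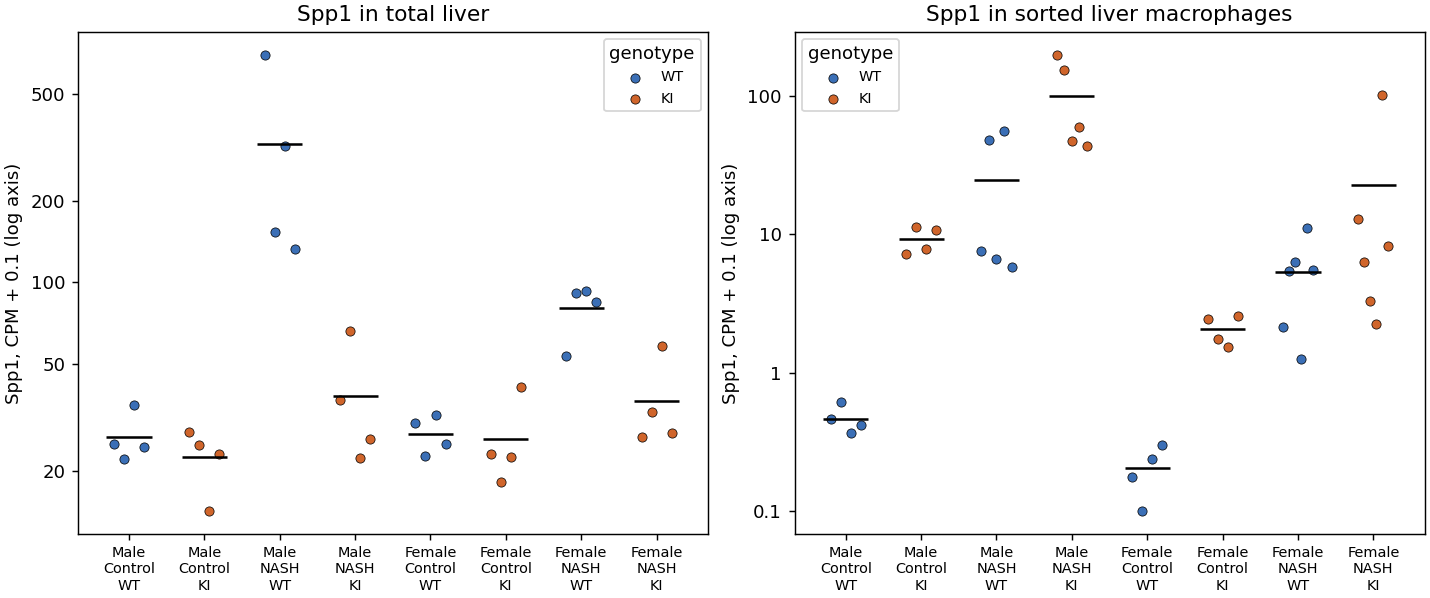
Spp1 in CPM over the library's total count, plus 0.1 and on a log axis, 1 point per deposited library and a bar at the group mean, by tissue, sex, genotype and diet. Both deposited versions of the duplicated male liver WT control library are drawn.

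The labels were checked against the counts. In genes with a summed count of 20 to 200 the male liver WT control replicates 3 and 4 differ by less than counting noise allows (mean chi-square per gene 0.06713, against 2.054 to 11.91 in the other 121 pairs of libraries within groups), so they stand as 1 library in 2 versions and that group has n = 3. The versions differ in abundant genes, with Alb at 26170 and 134100 CPM and a hepatocyte list mean of 10.88 and 12.04 log2 CPM, and their mean mixes the 2 levels. The library labelled male liver WT control 3 and 4 has the sex genes of a female, with 7035 and 8377 counts of Xist, the RNA of the inactive X, and 5 counts of the Y gene Ddx3y in each version. The library labelled macrophage male WT control 4 has 19051 counts of Xist and 9 of Ddx3y. The other male liver libraries have Xist up to 0.419 CPM and Ddx3y of 52.8 to 85.0 CPM, the other male macrophage libraries Xist up to 9.73 CPM and Ddx3y from 87.9 CPM. Lyz2, the lysozyme gene that carries Cre, stands at 2 levels in macrophages: 43 to 166 CPM in 10 libraries and 1473 to 3782 CPM in the other 28. The low libraries are male WT control 4, male KI control 3, female WT control 1, 3 and 4, female KI control 1, 2 and 3 and female KI NASH 3 and 4. All mice are labelled Lyz2.Cre+/+, and whether the libraries of either level come from another Lyz2.Cre genotype was not tested. Nor was it tested whether the Lyz2 differences between KI and WT given below reflect it. In liver, Lyz2 was at 1.05 to 2.58 CPM in all 8 female WT libraries, 19.9 to 43.4 CPM in female KI control and 1.26 to 69.0 CPM in female KI NASH. Male liver had 33.5 to 96.0 and 139 to 311 CPM in male WT control and NASH, and 0.48 to 26.8 and 1.10 to 54.9 CPM in male KI control and NASH.

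**Figure D2:**
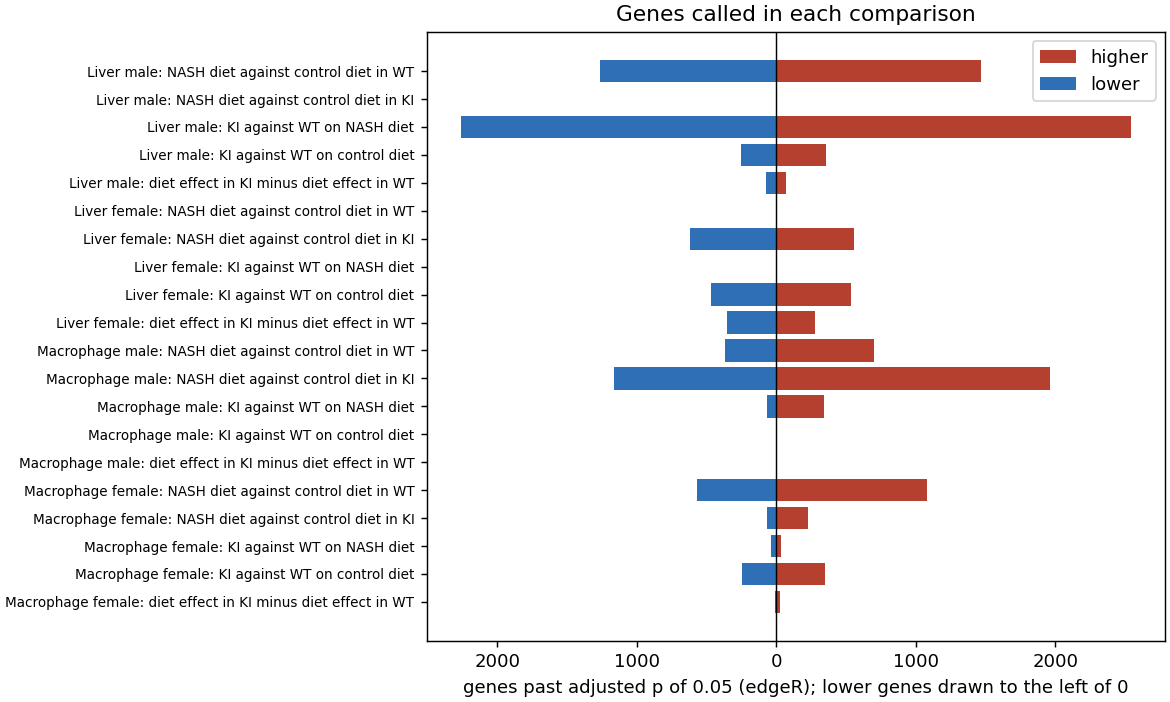
Genes higher (right) and lower (left) past the adjusted threshold of edgeR in the 5 comparisons of each tissue and sex. Comparisons with few or no genes show no visible bar.

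What does the NASH diet do to the liver of WT males? Spp1 rose (log2 fold change 3.38, adjusted p = 0.0014; 283 ± 201 CPM, mean and SD of n = 4, against 27.1 ± 1.66 CPM, n = 3), as did Cd44, an osteopontin receptor (1.16, adjusted p = 0.003; 25.8 ± 5.7 against 11.5 ± 1.69 CPM). The lipid droplet gene Cidea was at 62.2 ± 42.3 CPM against 0.0613 ± 0.0635 CPM, Sprr1a at 12.5 ± 3.48 against 0.0211 CPM and the glycerol channel Aqp7 at 5.00 ± 3.14 against 0.0422 CPM. Adgrf1 fell by 5.18 (0.65 ± 0.286 against 23.8 ± 22 CPM), the nuclear receptor Nr4a1 by 4.19 (5.29 ± 1.94 against 96.6 ± 96.9 CPM; 2.95 without WT control replicate 1) and the hepcidin gene Hamp2 by 3.77 (9.93 ± 3.2 against 136 ± 189 CPM; log2 fold change -1.40 without WT control replicate 3 and 4). Stat3 fell by 0.69 (adjusted p = 0.029), but not without WT control replicate 1 or 2 or WT NASH replicate 1, 2 or 3, and the imprinted H19 rose by 6.86, but not without WT control replicate 2, and by 3.27 without WT NASH replicate 1. Osmr, Arg2, Socs3, Cpt1a and Lyz2 did not pass, and Osm was too low to test in liver.

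By list, 25 of 28 extracellular matrix genes rose and 3 did not pass, 25 also when adjusted over the list alone (camera adjusted p = 7.7e-14, and adjusted p = 0.27 with an estimated correlation), with Col3a1 at 3.29, Col1a1 at 3.65 and the collagenase Mmp13 at 4.97. Of 17 lipid-associated macrophage genes 13 rose and 1 fell (14 and 1 over the list alone, camera adjusted p = 1.9e-09, and adjusted p = 0.052 with an estimated correlation), among them Mmp12 at 5.68, Trem2 at 3.57 and Gpnmb at 6.63. Of 10 MHC class II genes 8 rose (9 over the list alone), of 22 cell cycle genes 12 (17), among them Top2a at 3.10, of 11 cholangiocyte genes 7 (10), of 15 lipid droplet genes 8 (8), among them Mogat1 at 5.30, and of 20 PPARA targets 8 (8), each called by camera with adjusted p = 0.27 with an estimated correlation. Of 24 cholesterol genes 16 fell (18 over the list alone, camera adjusted p = 2.9e-09, and adjusted p = 0.27 with an estimated correlation), among them the sterol carrier gene Stard4 at -1.79. Hepatocyte genes fell 10 times of 18 (12 over the list alone), as with the urea cycle gene Cps1 at -1.62, and Cyp3a11 rose (3.00). The hepatocyte list, also called by camera, has adjusted p = 0.27 with an estimated correlation too.

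The fit called 2730 of 12988 genes, 1465 higher and 1265 lower, and 3376 without the library with contradicting sex genes. Leaving out WT control replicate 1 or 2 gave 1415 or 1123. That library also carries the fall of Cyp3a41a, a P450 of female mouse liver, from 164 ± 283 to 0.219 ± 0.0955 CPM, and has the immediate early gene Fos at 272 and 196 CPM in its versions against 6.28 and 9.22 CPM in WT control 1 and 2.

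In KI males the same diet left no gene past the threshold. Spp1 stood at 38.2 ± 19.8 CPM on the NASH diet and 23.1 ± 6.35 CPM on the control diet (n = 4 each; log2 fold change 0.72, adjusted p = 0.88). The 2 genes with the smallest p were the ubiquitin ligase Rnf145 (0.94, adjusted p = 0.11) and the phosphatase Phospho1 (1.32, adjusted p = 0.11). No member passed in any list over all genes. Adjusted over the list alone, 9 of 15 lipid droplet genes and 2 of 17 lipid-associated macrophage genes were higher, and camera called both lists (adjusted p = 3.7e-08 and 0.0029, but adjusted p = 0.23 and 0.32 with an estimated correlation). Of 12988 genes 847 had an unadjusted p under 0.05, and DESeq2 called 43. Without WT control replicate 3 and 4, or without KI NASH replicate 4, edgeR called 1.

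How do KI and WT males differ on the NASH diet? This was the largest contrast in liver: 4807 of 12988 genes, 2544 higher and 2263 lower in KI, and 5252 without the library with contradicting sex genes. Spp1 was lower in KI liver (-2.89, adjusted p = 0.00044; 38.2 ± 19.8 against 283 ± 201 CPM, n = 4 each). Stat3, the transducer of interleukin 6 family signals, was higher (0.95, adjusted p = 0.0021; 204 ± 53.5 against 106 ± 11.4 CPM). The hepatocyte list was not called (5 of 18 higher and 1 lower). Among the largest rises in KI were genes of hepatocytes, with the urinary protein gene Mup1 at 136 ± 165 against 1.51 ± 1.94 CPM (log2 fold change 6.47, and 5.16 without KI NASH 4), Hsd3b5 at 208 ± 113 against 6.26 ± 6.83 CPM (5.06) and Mug2 at 604 ± 180 against 16.6 ± 6.99 CPM (5.18). Moxd1 stood at 141 ± 118 against 0.118 ± 0.078 CPM. The macrophage glycoprotein Gpnmb was lower (-5.99, adjusted p = 0.00013; 0.538 ± 0.35 against 33.1 ± 17.3 CPM), as were H19 (-7.43, and -3.87 without WT NASH 1), Cyp2a4 (-7.04, and -4.39 without WT NASH 1; 1.29 ± 0.174 against 170 ± 286 CPM) and Sdcbp2 (-5.50; 0.125 ± 0.118 against 5.74 ± 3.88 CPM). Cd44 (-0.63, adjusted p = 0.018) was lower, but not without WT NASH replicate 1 or KI NASH replicate 1 or 3, and Lyz2 (-2.72, adjusted p = 0.037), but not without WT NASH replicate 1 or 2 or KI NASH replicate 1, 3 or 4. Osmr, Arg2, Socs3 and Cpt1a did not pass.

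Fibrosis genes were the most uniform group: 27 of 28 matrix genes were lower in KI (28 over the list alone, camera adjusted p = 3.6e-11, and adjusted p = 0.39 with an estimated correlation), among them Col3a1 at -2.84, Col1a2 at -2.63, Lum at -2.33 and the cytokine Tgfb1 at -0.82. Of 17 lipid-associated macrophage genes 13 were lower (14 over the list alone, and 1 higher; camera adjusted p = 2.4e-07, adjusted p = 0.12 with an estimated correlation), with Mmp12 at -4.67, Lgals3 at -2.50 and Trem2 at -2.97. Of 10 MHC class II genes 9 were lower (9, H2-Aa -2.48, H2-Eb1 -2.65), of 15 lipid droplet genes 9 (9, Mogat1 -3.88, Cd36 -2.47), of 20 PPARA targets 11 (12, Acot2 -2.60, Ehhadh -1.29), of 14 NRF2 and glutathione genes 7 lower and 1 higher (8 and 1, Nqo1 -2.00, Gpx4 -1.30) and of 21 lysosome genes 10 lower and 1 higher (10 and 3, Hexa -1.04, Ctss -1.31). Camera called each of these (adjusted p from 2.6e-05 to 0.035), with adjusted p = 0.39 for these 5 with an estimated correlation.

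Lists with adjusted p = 0.51 or 0.52 with an estimated correlation, and a camera call, were these. Of 11 cholangiocyte genes 9 were lower (Epcam -2.75), of 13 stellate cell genes 5 (Dcn -1.01, Lrat -0.76), of 15 NF-kB targets 5 (Ccl2 -2.81, Tnf -2.25), of 22 cell cycle genes 15 with 1 higher (Cdk1 -2.47), of 19 mitochondrial fatty acid oxidation genes 9 (Acadm -0.72) and of 7 B and plasma cell genes 2 (3 over the list alone, Cd79b -2.03). Of 15 unfolded protein response genes 7 were higher and 1 lower (8 and 1 over the list alone, the chaperone Hyou1 1.67, Trib3 -2.05). Of 24 cholesterol genes 6 were higher (4 over the list alone, Stard4 1.26) and of 28 oxidative phosphorylation genes 8 were lower (5 over the list alone, Uqcrfs1 -0.62), each with adjusted p = 0.62 with an estimated correlation. Unless given, the numbers over the list alone equal those over all genes.

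The remaining lists were not called by camera. Members passed as follows: hepatocyte 5 higher and 1 lower of 18 (Cps1 1.43, Cyp3a11 -2.24), acute phase 6 and 1 of 21 (Itih3 1.33, Il1rn -2.32), oncostatin M pathway 5 higher of 13 (Lifr 1.67, Il6st 0.78), bile acid 4 and 3 of 19 (Cyp7b1 3.08, Abcb4 -0.41), urea cycle 3 higher of 10 (Slc7a2 0.97), fatty acid synthesis 1 and 1 of 19 (Mlxipl 0.83, Scd2 -1.99), alternative activation 2 higher and 8 lower of 14 (Mertk 0.60, C1qa -0.92), recruited monocyte 2 and 5 of 14 (Fn1 1.46, Ccr2 -2.28), Kupffer cell 1 and 2 of 14 (Cd163 2.88, Id1 -2.33), neutrophil 3 higher of 9 (S100a9 1.49), T and NK cell 1 higher of 13 (Cd4 1.75), dendritic cell 2 lower of 8 (Cd209a -3.22), sinusoidal endothelial cell 2 lower of 14 (Pecam1 -0.39) and immediate early 1 and 2 of 15 (Dusp1 1.12, Klf6 -1.37). Over the list alone the counts differed for oncostatin M (6 higher), fatty acid synthesis (1 higher, none lower), recruited monocyte (7 lower) and immediate early (1 higher, none lower). None of 17 interferon genes passed (camera adjusted p = 0.2) and none of 2 erythroid genes, too few for camera. Fold changes across genes followed exonic length (Spearman 0.34; median -0.29 in the shortest quintile and 0.32 in the longest). No left-out library moved the count by 1.5 times (3799 to 5252).

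**Figure D3:**
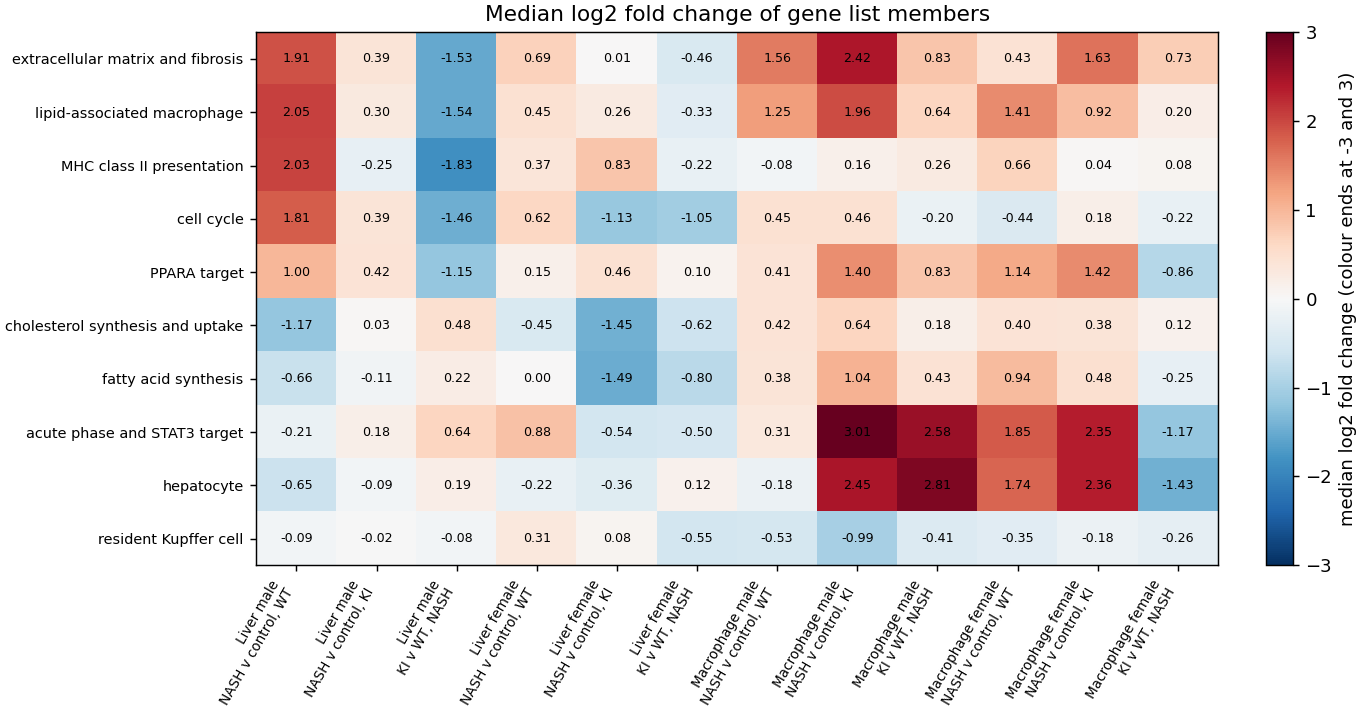
Median log2 fold change of the members of 10 gene lists for the diet effect in WT and in KI and for KI against WT on the NASH diet, in each tissue and sex. The values do not show which lists passed a test.

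On the control diet 606 genes differed between KI and WT male liver, 356 higher and 250 lower. Spp1 was not among them (-0.23, adjusted p = 0.81). Derl3, of endoplasmic reticulum degradation, was higher (3.85, adjusted p = 0.014; 36.8 ± 19.8 against 2.5 ± 1.14 CPM, n = 4 and 3), as was the death ligand Tnfsf10 (2.27, adjusted p = 0.014; 34.3 ± 12.6 against 7.13 ± 4.38 CPM). The clock gene Arntl was higher too (2.37, adjusted p = 0.019), but not without WT control replicate 1 or 2. Of 24 cholesterol genes 5 were lower (12 over the list alone, Sc5d -0.82), of 19 mitochondrial fatty acid oxidation genes 3 (12, Acadl -0.56) and of 28 oxidative phosphorylation genes 1 (14, Cox6c -0.56), with camera adjusted p = 8.6e-07, 1.1e-06 and 2.9e-08, and adjusted p = 0.82 for each with an estimated correlation. Of 15 immediate early genes 3 were lower (6, Jund -1.10, camera adjusted p = 0.0012 and also adjusted p = 0.82 with an estimated correlation). Of 15 unfolded protein response genes 2 were higher (7, and 1 lower, Creld2 1.96, Hyou1 1.28). The lower Cyp3a41a, Cyp2c69 and Cyp2c40 (164 ± 283, 219 ± 376 and 128 ± 212 CPM in WT) again come from the library with contradicting sex genes. Without it 695 genes were called, and 145 with the replicate block. Leaving out 8 of 15 libraries moved the count by over 1.5 times, to 107 (KI control 4), 140 (KI control 2), 151 (WT control 1), 265 (WT control 2), 302 and 393 (KI control 1 and 3), 387 (WT NASH 3) and 362 (KI NASH 3), and the Spearman correlation with exonic length was 0.34.

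The diet effect itself differed between KI and WT males for 147 genes, 72 more positive and 75 more negative in KI (626 without the library with contradicting sex genes). Spp1 had an interaction of -2.66 that did not pass (adjusted p = 0.067). Of 17 lipid-associated macrophage genes 5 had a more negative and 1 a more positive diet effect in KI (10 and 1 over the list alone, camera adjusted p = 4e-08, adjusted p = 0.10 with an estimated correlation). Of 10 MHC class II genes 3 were more negative (8), of 28 matrix genes 1 (21), and of 24 cholesterol genes 2 were more positive (14), with camera adjusted p = 3.6e-08, 1.9e-11 and 2.2e-09, each with adjusted p = 0.36 with an estimated correlation. Leaving out 1 library moved the count for 13 of 15, to between 18 and 82, except for the 626 given. Only WT NASH 4 and KI control 4 left it near 147.

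In liver of WT females 7 of 13315 genes passed with the diet, 5 higher and 2 lower. The 4 NASH libraries of this group lie far apart: replicates 1 to 4 stand at 31.6, 28.4, -29.3 and -19.0 on the first principal component, with Cdkn1a at 4.20, 1.88, 72.6 and 62.6 CPM and Igfbp1 at 11.3, 64.5, 738 and 275 CPM. The low count does not show a weak effect. The 7 genes were the desaturase Scd2 (2.11; 40.9 ± 13.9 against 9.48 ± 1.83 CPM, n = 4 each), Basp1 (1.20), the annexin Anxa2 (1.11), the basement membrane collagen Col4a2 (1.07; 42.8 ± 9.65 against 20.4 ± 3.79 CPM), the proteasome gene Psmd14 (0.60), Sox12 (-1.21) and Amigo1 (-0.92). Each had adjusted p = 0.039 and was lost when any of 8 to 10 of the 16 libraries was left out. Spp1 was at 79.2 ± 20.5 against 27.1 ± 3.98 CPM without passing (1.55, adjusted p = 0.058). Over the list alone 17 of 26 matrix genes were higher (1 over all genes), 7 lipid-associated macrophage genes, 6 of 9 cholangiocyte genes and 9 of 21 acute phase genes (none over all genes), with adjusted p = 0.25, 0.18, 0.072 and 0.37 with an estimated correlation. Camera called all 4 lists with the preset one. At an unadjusted p under 0.05 there were 1829 genes, and DESeq2 called 321. Leaving out 13 of 16 libraries gave 0 to 19 genes, or 117 without WT NASH replicate 1. KI control 3 and 4 and WT NASH 2 left it near 7.

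In KI females the diet moved 1176 genes, 560 higher and 616 lower, while Spp1 stayed (0.24, adjusted p = 0.63). Genes of lipid synthesis fell. Of 24 cholesterol genes 18 fell (23 over the list alone, camera adjusted p = 1.8e-11, and adjusted p = 0.66 with an estimated correlation), among them Sqle at -4.39 (5.32 ± 2.76 against 111 ± 88.5 CPM, n = 4 each) and Pmvk at -2.43 (24.3 ± 5.84 against 131 ± 73.8 CPM). Of 19 fatty acid synthesis genes 10 fell (12, camera adjusted p = 7.2e-07, and adjusted p = 0.66 with an estimated correlation), with Thrsp at -2.31, Acaca at -1.86 and Scd1 at -1.55, and of 10 urea cycle genes 4 fell (Asl -0.86). MHC class II genes rose, 3 of 10 (8 over the list alone, Ciita, their transactivator, 1.22). The urea cycle and MHC class II lists also have adjusted p = 0.66 with an estimated correlation. Outside them the lipid droplet proteins Plin4 (-3.52) and Plin5 (-2.18) fell, and the chemokine Ccl2 (2.31) and the macrophage elastase Mmp12 (2.89) rose. The count was 568, 466, 493, 500 and 634 without KI control 3, KI control 4, KI NASH 2, KI NASH 3 and KI NASH 4.

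KI and WT female livers on the NASH diet differed in 12 genes, 9 higher and 3 lower in KI. Osmr, the oncostatin M receptor, was lower (-1.21, adjusted p = 0.046; 4.64 ± 0.742 against 10.7 ± 2.61 CPM, n = 4 each), the only member of any list to pass. It was lost in 11 of 16 refits with a library left out. Trim6, a ubiquitin ligase, was higher (3.78, adjusted p = 0.0039; 7.99 ± 4.98 against 0.571 ± 0.154 CPM), and its neighbour Trim34b stood at 2.09 ± 0.65 against 0.0217 ± 0.025 CPM. The serpin Serpina11 was higher (1.75, adjusted p = 0.022; 173 ± 57.4 against 51.5 ± 8.06 CPM), but not without KI NASH 2 or 3 or WT NASH 1, 2 or 4, and the sulfotransferase Sult2a6 stood at 0.0134 ± 0.0268 against 13.8 ± 3.62 CPM. Spp1 did not pass (-1.22, adjusted p = 0.16; 33.9 ± 12.8 against 79.2 ± 20.5 CPM). Over the list alone 3 of 17 interferon genes were higher, 3 of 26 matrix genes lower and 4 of 19 fatty acid synthesis genes lower. Camera called these lists (adjusted p = 2.4e-07, 8.3e-08 and 4.6e-06), each with adjusted p = 0.37 with an estimated correlation. At an unadjusted p under 0.05 there were 1728 genes, and DESeq2 called 156. The count was 29 without KI NASH 1, 6 without KI NASH 2 or 3 and 5 without WT NASH 4.

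On the control diet 1008 genes differed between KI and WT female liver, 538 higher and 470 lower. The cell cycle inhibitor Cdkn1a was higher in KI (5.83, adjusted p = 0.0063; 162 ± 71.4 against 2.85 ± 1.45 CPM, n = 4 each), as were Fam107a (5.6, adjusted p = 0.012; 19.1 ± 14 against 0.39 ± 0.539 CPM), Arg2 (2.57, adjusted p = 0.017, lost without WT control 3) and Lyz2 (4.15, adjusted p = 0.018, lost without WT control 1 or 3; 33.3 ± 9.19 against 1.87 ± 0.574 CPM). Stat3 (0.90, adjusted p = 0.047) was lost in 9 refits. Serpina3c stood at 112 ± 52.1 against 0.0462 CPM, Sult2a6 at 0 against 6.01 ± 5.34 CPM, and Rpl29 was lower (-3.78, adjusted p = 0.0033, 2.03 ± 0.601 against 28 ± 7.11 CPM). Acute phase genes were higher, 5 of 21 (9 over the list alone, Lcn2 4.07, Serpina3n 1.95), as were 4 of 17 interferon (5, Usp18 1.34), 4 of 12 recruited monocyte (4, Ly6c2 1.21) and 3 of 9 neutrophil genes (5, Mmp8 3.60). Camera called these (adjusted p = 8.6e-05, 0.00039, 0.0042 and 0.0012), each with adjusted p = 0.80 with an estimated correlation. The count was 651, 488 and 503 without KI control 2, 3 and 4, and 393, 395 and 510 without WT control 1, 3 and 4.

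The diet effect differed between KI and WT females for 635 genes, 280 more positive and 355 more negative in KI. Osmr was among them (-1.46, adjusted p = 0.019). Of 21 acute phase genes 8 were more negative (11 over the list alone, Lcn2 -7.11, Saa2 -7.90), of 19 fatty acid synthesis genes 5 (11, Thrsp -2.70) and of 24 cholesterol genes 1 (12), and the lipid droplet gene Plin4 had -5.03. Camera adjusted p were 1e-05, 1e-05 and 0.00037, each with adjusted p = 0.70 with an estimated correlation. Left-out libraries moved the count for 12 of 16, to 254 to 404, except 1198 and 992 without WT NASH 1 and 2.

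Averaged over sexes, 4038 of 13415 genes differed between KI and WT liver on the NASH diet, 2165 higher and 1873 lower, 4255 without the library with contradicting sex genes. No left-out library moved this by 1.5 times, and the Spearman correlation with exonic length was 0.26. Spp1 was lower in KI (-2.03, adjusted p = 1.5e-05; n = 8 each), as was Osmr (-0.75, adjusted p = 0.011), and Cpt1a, the entry of fatty acids into mitochondria, was higher (0.41, adjusted p = 0.029), but not without male WT NASH 1, male KI NASH 1 or female WT NASH 3. The death ligand Tnfsf10 (2.42), Serpina11 (2.08) and Cyp2u1 (1.81) were higher, and the stress protein Nupr1 (-2.92) and the P450 Cyp2b10 (-2.81) lower. Of 17 lipid-associated macrophage genes 12 were lower (14 over the list alone, Lgals3 -1.40, Mmp12 -2.61), a camera call kept with an estimated correlation (adjusted p = 1.6e-08 and 0.026), but mostly one of males (median -1.54, against -0.33 in females). Of 28 matrix genes 25 were lower (26, Col1a2 -1.76, Sparc -0.99), of 10 MHC class II genes 7 (10, H2-Aa -1.33) and of 11 cholangiocyte genes 10 (10, Epcam -1.97), with adjusted p = 0.27, 0.27 and 0.28 with an estimated correlation. Of 22 cell cycle genes 16 were lower (17, Ccnb2 -2.48), and of 15 NRF2 genes 8 were lower and 1 higher (9 and 1, Nqo1 -1.25). Their adjusted p were 0.48 and 0.20 with an estimated correlation.

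Do the sexes differ in these effects? The KI effect on the NASH diet differed for 1880 genes, 705 more positive and 1175 more negative in females. Spp1 (1.64) and 10 of 17 lipid-associated macrophage genes were more positive (11, and 1 more negative, over the list alone, camera adjusted p = 1.1e-06, adjusted p = 0.078 with an estimated correlation), as were 10 of 28 matrix genes (18) and 5 of 10 MHC class II genes (7), both with adjusted p = 0.45 with an estimated correlation. Stat3 was more negative (-1.11), as were 8 of 21 acute phase genes, with 1 more positive (12 and 1 over the list alone, adjusted p = 0.52 with an estimated correlation). The diet effect in WT differed for 225 genes (114 and 111, and 664 without the library with contradicting sex genes), and 2 of 17 lipid-associated macrophage genes were more negative in females (8 over the list alone), a list call kept with an estimated correlation (adjusted p = 3.8e-08 and 0.027). Left-out libraries moved this count for 12 of 31, to 73 to 664, and moved 1880 only to 1311 to 2147. The KI difference had a Spearman correlation of -0.34 with exonic length. Across genes, which are not independent replicates, the male and female fold changes had a Pearson correlation of 0.45 for the diet in WT and 0.32 for KI on the NASH diet. These rest on different animals, and 4 and 6 genes were higher in both sexes where 0.544 and 1.78 are the numbers chance gives.

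In macrophages of WT males the NASH diet moved 1068 of 13036 genes, 699 higher and 369 lower. Spp1 rose (5.95, adjusted p = 0.0077; 24.2 ± 24.5 against 0.383 ± 0.12 CPM, n = 5 and 4), and so did Osm, the cytokine oncostatin M (3.89, adjusted p = 0.011; 9.81 ± 8.6 against 0.638 ± 0.577 CPM), and the adhesion molecule Sele (4.52, adjusted p = 0.0099; 11.8 ± 8.7 against 0.508 ± 0.0982 CPM). Slc27a6, a fatty acid transporter, fell (-2.34, adjusted p = 0.0068; 3.39 ± 1.47 against 17.1 ± 6.23 CPM), as did Mturn (-2.43, adjusted p = 0.0068; 2.49 ± 1.06 against 13.3 ± 4.58 CPM). Osmr (2.61) rose, but not without WT control 2, 3 or 4 or WT NASH 4, Gpnmb (6.61), but not without WT control 3 or 4, and Cd44 fell (-0.50, adjusted p = 0.039), but not in 9 refits. Of 17 lipid-associated macrophage genes 6 rose (12, and 1 lower, over the list alone, Cd9 2.87, Trem2 2.12), of 14 sinusoidal endothelial genes 10 (10, Tek 2.55, Fcgr2b 2.10), of 28 matrix genes 7 (12, Col4a1 2.44) and of 10 dendritic cell genes 4 (7, Flt3 3.46), each called by camera with adjusted p = 0.56 with an estimated correlation. Of 15 alternative activation genes 6 fell (9, and 1 higher, C1qa -0.55, Clec10a -0.59), and of 14 Kupffer cell genes 3 (4, Slc40a1 -1.02, Spic -0.55). Camera called these 2 too, also with adjusted p = 0.56 with an estimated correlation, and of 14 T and NK cell genes 3 rose (11, Klrb1c 3.85; adjusted p = 0.69). Endothelial, lymphoid and dendritic markers thus moved with the matrix and lipid-associated macrophage genes.

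Without the library labelled macrophage male WT control 4, with its contradicting sex genes, 284 genes passed, and 524, 83, 298 and 277 without WT control 1, 2 and 3 and WT NASH 4.

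In macrophages of KI males the diet moved 3127 genes, 1962 higher and 1165 lower. Spp1 rose (3.43, adjusted p = 0.0034, 99.9 ± 71.6 against 9.25 ± 2.09 CPM, n = 5 and 4), as did Osm (3.72, adjusted p = 0.0012; 41.8 ± 11 against 3.15 ± 1.23 CPM), Osmr (2.39, adjusted p = 0.012) and Socs3, a feedback inhibitor of STAT3 (1.26, adjusted p = 0.011; 353 ± 145 against 147 ± 35.7 CPM). Kupffer cell identity genes fell, 10 of 14 (11 over the list alone, Timd4 -2.08, Folr2 -1.13, Nr1h3 -0.67), and lipid-associated macrophage genes rose, 14 of 17 with 1 falling (15 and 1, Cd9 4.30, Trem2 3.38, Gpnmb 9.34), both with adjusted p = 0.22 with an estimated correlation. Matrix genes rose, 21 of 28 (25, Col1a1 5.81, Mmp2 2.73; also adjusted p = 0.22). Of 20 NF-kB targets 10 rose (12, Tnf 2.56, Nfkbia 1.13; adjusted p = 0.59 with an estimated correlation). Markers of other cells rose with them: 15 of 18 hepatocyte genes (16, Cyp2e1 4.48; adjusted p = 0.37 with an estimated correlation), 15 of 18 acute phase genes (15), 14 of 19 bile acid genes with 1 falling (15 and 1) and 11 of 18 PPARA targets (11), each of these 3 with adjusted p = 0.22, and 12 of 14 T and NK cell genes (13, adjusted p = 0.40). A covariate of the hepatocyte list left 205 genes, and no left-out library moved the count by 1.5 times (2224 to 3991).

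Between KI and WT male macrophages on the NASH diet 408 genes differed, 342 higher and 66 lower in KI. Spp1 was at 99.9 ± 71.6 against 24.2 ± 24.5 CPM (n = 5 each) without passing (2.05, adjusted p = 0.089). Osm was higher in KI (2.09, adjusted p = 0.040; 41.8 ± 11 against 9.81 ± 8.6 CPM), though not in 11 of 18 refits. So was the urea cycle gene Arg1 (2.22, adjusted p = 0.018; 19.6 ± 11.5 against 4.22 ± 1.85 CPM). Most genes with large rises were of hepatocytes: Cyp2c37 (4.06; 4.13 ± 4.95 against 0.239 ± 0.149 CPM), Cyp1a2 (3.76), Dio1 (3.70) and Aadat (3.59), each lost without WT NASH 1 or 5, and the first 3 at 2.98, 2.74 and 2.59 without KI NASH 4. Of 18 hepatocyte genes 15 were higher (17 over the list alone, camera adjusted p = 1.4e-18), with Ahsg at 2.82 and Cyp2e1 at 3.25, of 18 acute phase genes 10 (14, 5.5e-13; Fgg 3.05) and of 19 bile acid genes 10 (13, 2.5e-09; Abcg8 3.38), all with adjusted p = 0.16 with an estimated correlation. Of 18 PPARA targets 4 were higher (10, and 1 lower, Fabp1 2.51) and of 14 Kupffer cell genes 1 lower (3, Nr1h3 -0.33), with adjusted p = 0.28. Among the lower genes were the interferon-induced GTPase Gbp2b (-1.18; 99.7 ± 17.4 against 226 ± 45.1 CPM) and Cd300e (-0.96; 69.7 ± 21 against 136 ± 27.4 CPM), also lost without WT NASH 1 or 5. With the hepatocyte list as a covariate 0 genes were called, and 384 without the library with contradicting sex genes. The count was 0 without WT NASH 1 or 5, 147, 262 and 975 without WT NASH 2, 3 and 4, and 89 and 800 without KI NASH 4 and 5.

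On the control diet no gene passed between KI and WT male macrophages. Spp1 was at 9.25 ± 2.09 against 0.383 ± 0.12 CPM (n = 4 each; 4.56, adjusted p = 0.64), with no overlap between the groups. Over the list alone 7 of 14 sinusoidal endothelial genes were higher (camera adjusted p = 9.7e-10, adjusted p = 0.96 with an estimated correlation). At an unadjusted p under 0.05 there were 862 genes, DESeq2 called 4, and without WT control 2 edgeR called 1. For the difference of the diet effect between KI and WT no gene passed with edgeR either (Spp1 -2.52, adjusted p = 0.40). There 16 of 18 hepatocyte genes were more positive in KI over the list alone (camera adjusted p = 2.8e-13, adjusted p = 0.27 with an estimated correlation), 1595 genes had an unadjusted p under 0.05 and DESeq2 called 249. Without WT control 2 edgeR called 1.

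In macrophages of WT females the diet moved 1652 of 12838 genes, 1084 higher and 568 lower. Spp1 rose (5.61, adjusted p = 0.015; 5.37 ± 3.73 against 0.101 ± 0.0821 CPM, n = 6 and 4), as did Osm (4.62, adjusted p = 0.00037; 6.16 ± 2.21 against 0.252 ± 0.069 CPM), the growth factor Gdf3 (5.86, adjusted p = 7.9e-07; 72.3 ± 26.8 against 1.24 ± 0.259 CPM), Gpnmb (6.64, adjusted p = 0.0036; 127 ± 84.9 against 1.27 ± 0.303 CPM) and the elastase Mmp12 (5.21, adjusted p = 0.00079; 570 ± 406 against 15.5 ± 2.02 CPM). The scavenger receptor Marco fell (-3.0, adjusted p = 0.013; 187 ± 101 against 1500 ± 512 CPM), as did the lectin Cd209f (-3.65) and Cd55 (-3.21). Socs3 rose (1.18), but not without any WT control or WT NASH 5. Lipid-associated macrophage genes rose, 10 of 17 (14 over the list alone, Cd9 3.61, Apoe 1.10), as did 11 of 16 bile acid genes (12), both with adjusted p = 0.19 with an estimated correlation. Of 20 NF-kB targets 12 rose (14) and of 18 hepatocyte genes 9 (14, Cyp3a11 4.95), with adjusted p = 0.30. Of 16 acute phase genes 10 rose (13, and 1 lower, adjusted p = 0.28) and of 15 immediate early genes 6 (8, adjusted p = 0.29). Interferon genes fell, 4 of 17 (6, adjusted p = 0.57), and so did 3 of 14 Kupffer cell genes (3, Timd4 -1.31), with adjusted p = 0.39 with an estimated correlation. Lyz2 was at its low level in 3 of 4 control and in none of 6 NASH libraries, so that it goes with the diet here. With the hepatocyte list as a covariate 98 genes were called, with Lyz2 as one 344. Leaving out WT control 1 to 4 gave 784, 782, 768 and 900, and WT NASH 3 and 5 gave 983 and 1061.

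In macrophages of KI females 297 genes moved with the diet, 230 higher and 67 lower. Osm rose (2.15, adjusted p = 0.023; 23.7 ± 16.4 against 5.32 ± 2.18 CPM, n = 6 and 4), but not without KI control 1 or 3, and Spp1 did not pass (3.46, adjusted p = 0.056; 21.6 ± 37.2 against 1.94 ± 0.45 CPM; 1.75 without KI NASH 5). Of 18 PPARA targets 8 rose (12 over the list alone), of 18 hepatocyte genes 6 (16), of 13 stellate cell genes 6 (9), of 17 lipid-associated macrophage genes 3 (9) and of 26 matrix genes 3 (19). Camera called each of these, with adjusted p = 0.14 with an estimated correlation. Hepatocyte and stellate cell markers thus moved together with the macrophage genes. Lyz2 was low in 3 of 4 control and 2 of 6 NASH libraries. A covariate of the hepatocyte list left 2 genes, as did the replicate block, and one of Lyz2 34. Left-out libraries moved the count for 13 of 20, to 4 (KI control 3) to 688 (KI NASH 4). Across genes the diet effects of males and females correlated at 0.77 in KI and 0.49 in WT macrophages, from different animals, and 174 and 130 genes were higher in both sexes where chance gives 32.1 and 54.9.

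KI and WT female macrophages on the NASH diet differed in 72 genes, 36 higher and 36 lower in KI. Osm was higher (1.94, adjusted p = 0.047; 23.7 ± 16.4 against 6.16 ± 2.21 CPM, n = 6 each), as were the antiviral Oas1b (0.88) and Skp2 (0.61), and the sugar transporter Slc2a6 (-1.09) and Pmp22 (-0.66) were lower. All of these were lost in 14 to 18 of 20 refits with a library left out, those without any control library, WT NASH 1, 4, 5 or 6 or KI NASH 3 or 4 included. Spp1 did not pass (2.01, adjusted p = 0.16; 21.6 ± 37.2 against 5.37 ± 3.73 CPM), and stood at 0.28 without KI NASH 5. NF-kB targets were lower in KI, 4 of 20 (18, and 1 higher, over the list alone, camera adjusted p = 3.1e-14, adjusted p = 0.15 with an estimated correlation), with the cytokines Tnf at -2.02 and Il1a at -1.28 and the inhibitor Nfkbia at -1.31. Over the list alone 18 of 18 hepatocyte genes were lower and 10 of 13 T and NK cell genes higher, none of them over all genes (camera adjusted p = 6.2e-12 and 8e-09; adjusted p = 0.18 and 0.16 with an estimated correlation). Of 15 immediate early genes 1 was lower (10, and 1 higher, adjusted p = 0.18). The count was 0 with no filter on low counts, 21 with DESeq2 size factors, 6 with the replicate block, 146 with the hepatocyte list as a covariate and 0 with Lyz2 as one. Leaving out 19 of 20 libraries moved the count, to 0 except 116 (WT NASH 3), 14, 662, 234 and 9 (KI NASH 1, 2, 5 and 6). WT NASH 2 did not move it.

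On the control diet 596 genes differed between KI and WT female macrophages, 351 higher and 245 lower. Osm was higher in KI (4.41, adjusted p = 0.00076; 5.32 ± 2.18 against 0.252 ± 0.069 CPM, n = 4 each), as were Gdf3 (5.98, adjusted p = 8.6e-07; 78.7 ± 45.2 against 1.24 ± 0.259 CPM) and the chemokine receptor Ccr1 (5.6, adjusted p = 0.0047; 10.6 ± 13.1 against 0.221 ± 0.12 CPM, and 4.28 without KI control 3). Spp1 had no overlap between groups and did not pass (4.16, adjusted p = 0.10; 1.94 ± 0.45 against 0.101 ± 0.0821 CPM). Stellate cell genes were lower, 10 of 13 (11, and 1 higher, over the list alone, camera adjusted p = 4e-11, adjusted p = 0.28 with an estimated correlation), with the retinol enzyme Lrat at -2.63 and Colec11 at -2.39. Beside them 3 of 18 hepatocyte genes (16) and 3 of 22 cell cycle genes (21) were lower and 1 of 13 T and NK cell genes (10) was higher, each called by camera with adjusted p = 0.38 with an estimated correlation. A covariate of the hepatocyte list left 348 genes. The count was 311, 321, 307 and 282 without WT control 1 to 4, and 312, 261 and 919 without KI control 1, 2 and 4.

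The diet effect differed between KI and WT females for 37 genes in macrophages, 25 more positive and 12 more negative in KI. Stellate cell genes were more positive, 4 of 13 (12 over the list alone, camera adjusted p = 1.5e-16, adjusted p = 0.063 with an estimated correlation), and over the list alone 8 of 17 interferon genes were (camera adjusted p = 1.1e-06, adjusted p = 0.72). At an unadjusted p under 0.05 there were 1178 genes and DESeq2 called 157. With Lyz2 as a covariate 12 genes were called, and leaving out 15 of 20 libraries gave 5 to 23.

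Averaged over sexes, 140 of 13373 genes differed between KI and WT macrophages on the NASH diet, 58 higher and 82 lower. Osm was higher in KI (2.01, adjusted p = 0.0045; n = 11 each), in every refit with a library left out, and Spp1 too (2.01, adjusted p = 0.049), though not in 30 of 38 such refits. Of 28 matrix genes 4 were higher (15 over the list alone) and of 14 Kupffer cell genes 1 was lower (7), called by camera with adjusted p = 1.7e-08 and 2e-07, and adjusted p = 0.68 for each with an estimated correlation. Markers of other cells moved too: camera called the T and NK cell (median log2 fold change 1.30, camera adjusted p = 1.4e-05), stellate cell (0.27, 0.0032), hepatocyte (0.65, 0.0072), B and plasma cell (1.21, 0.030) and dendritic cell (0.68, 0.036) lists, without a member past the threshold over all genes and with adjusted p = 0.68 for each with an estimated correlation. The hepatocyte list goes opposite ways in the sexes (median 2.81 in males and -1.43 in females), so that its average describes neither. The T and NK cell list was at 0.25 in males and 2.50 in females. The count was 79 with DESeq2 size factors (43 higher and 36 lower, so the majority turns), 21 with no filter on low counts, 40 without the library with contradicting sex genes, 5 with the hepatocyte list as a covariate, 16 with Lyz2 as one, and 5 to 922 in 35 of the 38 leave-one-out refits.

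The KI effect on the NASH diet differed between the sexes for 584 macrophage genes, 55 more positive and 529 more negative in females. Hepatocyte genes were more negative, 17 of 18 (18 over the list alone, camera adjusted p = 8.2e-30), as were 12 of 19 acute phase genes (15), 11 of 19 bile acid genes (13) and 3 of 12 lipid droplet genes (7), list calls kept with an estimated correlation (adjusted p = 0.010 each). Of 19 PPARA targets 7 were more negative (11) and of 10 urea cycle genes 5 (8), also kept (adjusted p = 0.015 and 0.018). Of 20 NF-kB targets 11 were more negative (16, camera adjusted p = 8.4e-16, adjusted p = 0.053 with an estimated correlation). Of the 368 camera calls of all comparisons 8 are kept with an estimated correlation, these 6 and the lipid-associated macrophage list in liver averaged over sexes and in the sex difference of the liver diet effect. With the hepatocyte list as a covariate none of the 584 genes is called, and 385 are without male KI NASH 4. The diet effect in WT differed between the sexes for 3 genes, 2 more positive and 1 more negative, and for 1 to 118 in the 19 of 38 leave-one-out refits that moved it. DESeq2 called 265.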

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

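The tests of the hepatocyte transcripts, of a swap, of a mix of RNA and of a female animal in liver, and that of an effect shared by both sexes, were chosen only after the results were seen. Those of the macrophage sex score, of chromosome positions, of Lyz2 and of the splits were written before.

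Hepatocyte genes were higher in KI than in WT male macrophages on the NASH diet (15 of the 18 genes measured in macrophages, median log2 fold change 2.81, with Cyp2e1 at 77.5 ± 76.8 and Ahsg at 77.1 ± 62.9 CPM), and the gate on F4/80high CD11blow cells should remove hepatocytes. RNA of hepatocytes in the sorted cells is a candidate explanation: of 342 genes called higher, 319 (93.3%) rose within 3 times what an added 1.14% of liver RNA would bring. A further 16, among them Igfbp1, rose by more, for which it may not suffice, and 7 were not tested in liver, Osm, Il23a and Cyp2c23 among them. A lower share of macrophages, with all other liver cells gained alike, cannot be told apart from it: the ratio of the sinusoidal endothelial median (0.35) to the hepatocyte median was 0.12, but those genes stand higher in the macrophages than in liver, and that share of liver RNA would raise the endothelial list by 0 and the stellate list by 0.06. Whether hepatocyte RNA came by uptake in the animal, by attached cells or by ambient RNA of the sort was not tested.

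The library labelled male liver WT control 3 and 4 and the library labelled macrophage male WT control 4 have the sex genes of a female. No library labelled female (0) has more Ddx3y than Xist, which argues against a swap inside the series, and Ddx3y was at most 0.64% of the mean of the other males, which argues against a mix of RNA. A female animal under a male label may be the source, but autosomal genes that differ by sex place the liver library at 0.46 between the other males (-0.01 and 0.01) and the females (0.96 to 1.07), between the bounds set, so this cannot be told apart from a wrong sample of another kind, although Mup20 at 35.0 and 24.0 CPM (824 to 2133 CPM in the other male and 13.0 to 71.3 CPM in the female livers) and the P450s Cyp3a41a, Cyp2c69 and Cyp2c40 go with a female. For macrophages a value under 0.25 was to speak against it, and the library stood at -1.01. That bound could not decide, because the other males (-1.95 to 2.52) and the females (-0.30 to 2.29) overlap on this score, although Mup20 at 0.21 CPM (3.88 to 351 CPM in the other male and 0 to 3.92 CPM in the female macrophages) goes with a female here too.

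In female liver 9 genes differed between KI and WT on both diets: Serpina11, Serpina3c, H2-T24, Gm11127, Gm8909, 4932438A13Rik, Sult2a6, Trim6 and Trim34b. None (0) lies within 20 Mb of Lyz2. By the labels all mice carry Lyz2.Cre+/+, so a segment around the Cre insertion would not separate KI from WT, and this test cannot decide. A segment around the osteopontin knock-in itself was not tested. All but 4932438A13Rik and Sult2a6 form 5 pairs within 5 Mb on chromosomes 12, 17 and 7. Random sets have a median of 0 and a 95th percentile of 1 (0 of 10000 had as many). For those in pairs, a strain variant or segment carried with the genotype is a candidate explanation. Of 8 tested in male liver on the NASH diet 5 passed in the same direction, which an effect of the genotype shared by both sexes would give too, but 4932438A13Rik passed in the opposite one (0.62, adjusted p = 0.0011, against -0.73 in females), and 4807 of all 12988 genes pass there. The pairs are members of gene families, and reads shared between paralogs were not tested.

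Other splits of the libraries were tried for each count, and the number with as many genes, the real split included, is given with the highest of the others. In interactions and sex differences the other splits were fitted with the true genotype or sex as a covariate. The real split, whose groups already separate them, was fitted without it, so those counts are not fully comparable. Chance can be excluded in male liver for the diet in WT (2730 genes, 1 of 35 splits, highest other 1014), KI on the NASH diet (4807, 1 of 35, 3), KI on the control diet (606, 1 of 35, 5) and the interaction (147, 1 of 100, 88). So it was in female liver for the diet in KI (1176, 1 of 35, 79), KI on the control diet (1008, 1 of 35, 0) and the interaction (635, 3 of 100, 1446). In male macrophages it was for the diet in WT (1068, 1 of 100, 246) and in KI (3127, 2 of 100, 3513). In female macrophages it was for the diet in WT (1652, 1 of 100, 63) and in KI (297, 1 of 100, 264), KI on the NASH diet (72, 1 of 100, 18), KI on the control diet (596, 1 of 35, 6) and the interaction (37, 2 of 100, 40). Over both sexes it can for the averaged KI effect in liver (4038, 1 of 100, 3124), the liver sex difference of the diet effect (225, 4 of 100, 1258) and of the KI effect (1880, 1 of 99, 1149), and the macrophage sex difference of the KI effect (584, 3 of 100, 1620).

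The share was 0.05 or more, so that the splits do not speak against chance, for the diet in WT female liver (7, 2 of 35, 234), KI on the NASH diet in female liver (12, 2 of 35, 23), KI on the NASH diet in male macrophages (408, 5 of 100, 1518), the averaged KI effect in macrophages (140, 7 of 100, 859) and the macrophage sex difference of the diet effect (3, 18 of 100, 5). For the 3 counts of 0 with edgeR the splits say nothing about chance, since every split calls at least 0: the diet in KI male liver (35 of 35, 5, with 847 genes at an unadjusted p under 0.05 and 43 by DESeq2), KI on the control diet in male macrophages (35 of 35, 1, with 862 and 4) and the interaction there (100 of 100, 455, with 1595 and 249). A split that calls several times the real count, as with 234, 1258, 1518 and 859, or 455 where the real count is 0, points to a structure of the samples, which was not tested.

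Differences of effects that passed are log2 values, and those of genes near 0 CPM in a group depend on the prior count. In the male liver interaction they were Moxd1 10.61, Cyp2c40 8.81 (4.18 without the WT control library with contradicting sex genes), Fosb 5.27, Gpnmb -7.95, Mmp12 -5.30 and Gprc5b -4.77. In the female liver interaction they were Osmr -1.46, Arrdc3 3.78, Rpl29 3.12, Rnf43 3.06, Fam107a -10.08 (-7.90 without WT NASH 3), Adcy1 -8.62 and Sult1e1 -8.03, and in that of female macrophages Igfbp3 3.96, Disp2 3.21, Gdf3 -5.16, Clcf1 -2.63 and Ldlrad3 -2.61. Between the sexes, female minus male, the liver diet effect had Cyp3a16 14.88, Sult2a3 13.82, Sult2a1 12.05 (5.91, 6.85 and 3.21 without the male library with contradicting sex genes), Shc2 -6.27, Themis -4.69 and Ephb2 -4.64. The liver KI effect had Spp1 1.64, Stat3 -1.11, Lyz2 6.53, Cyp2a4 6.49 (3.85 without male WT NASH 1), Ankrd55 5.89 (3.35 without female KI NASH 3), Sult1e1 -7.78, Saa2 -6.15 and Mug2 -5.35. In macrophages the diet effect had Rcbtb2 0.95 and Dbr1 -0.80, and the KI effect Wfdc18 1.51, Prox2 1.23, Sectm1a 1.12, Il23a -6.71, Igfbp1 -6.56 and Cyp2c37 -5.84.

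Single libraries stood apart from their group in 41 of 367 groups of values tested, where chance gives about 1 in 20, or 18.4. In CPM, with the range of the others, male liver WT NASH 1 had Cd44 34.2 (22.2 to 24.2), Gipc2 18.4 (1.49 to 3.88), H19 376 (6.68 to 10.2), Cyp2a4 599 (15.1 to 39.1) and Lrtm2 6.76 (0.629 to 0.908). Elsewhere in male liver these were WT NASH 2 Cyp2c40 4.92 (0.218 to 0.943), KI control 1 Stat3 287 (166 to 184), KI control 3 Cyp2c40 1.62 (0.655 to 0.801), KI control 4 Fosb 0.56 (0.303 to 0.327) and KI NASH 1 H19 1.00 (0.371 to 0.473). Female liver had WT control 1 Cd44 14.4 (17.7 to 18.3), WT control 2 Fam107a 1.19 (0.0451 to 0.233), WT control 4 Cpt1a 1040 (640 to 681), WT NASH 1 Basp1 4.53 (6.52 to 6.78), WT NASH 3 Fam107a 8.57 (0.216 to 1.16), WT NASH 4 Anxa2 18.1 (26.8 to 28.4), KI NASH 1 Sult2a6 0.0535 (0 in the others), KI NASH 3 Spp1 52.9 (26.1 to 30.2) and KI NASH 4 Socs3 63.6 (7.23 to 12.5).

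In male macrophages KI NASH 4 had Cyp2c37 12.8 (0.475 to 3.39), Cyp1a2 14.3 (1.28 to 4.18), Cyp2d13 6.49 (0.808 to 1.68), Dio1 7.91 (0.713 to 1.89), Aadat 6.02 (0.475 to 1.68) and Fah 21.1 (4.48 to 8.35). The others were WT control 1 Arg2 136 (73.7 to 84.0), WT control 2 Gpnmb 9.76 (0.657 to 1.25) and Cyp2c37 1.33 (0.321 to 0.462), WT NASH 2 Cxcl13 11 (38.2 to 47.9), WT NASH 4 Sele 26.7 (4.71 to 10.8), KI NASH 1 Lyz2 3800 (1560 to 2020), KI NASH 5 Cpt1a 314 (212 to 235) and KI control 3 with a total count of 22247674 (16512356 to 17421214). Female macrophages had WT control 2 Lyz2 2650 (92.1 to 168), WT control 4 Arg2 25.9 (86.8 to 91.7), KI control 2 Fam71a 0.664 (0.157 to 0.211), KI control 4 Stat3 193 (229 to 236) and Lyz2 2840 (73.8 to 93.2), KI NASH 2 Osmr 14.8 (2.16 to 5.14) and Socs3 230 (68.2 to 85.2), and KI NASH 5 Spp1 97.1 (2.21 to 12.9).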

How the results depend on the processing

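The settings with both versions of the duplicated library, its fuller version, no library of contradicting sex genes and Lyz2 as a covariate were chosen only after the data were seen. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated over 0.1 in 5 of 18 pairs in male liver (-0.13 to 0.23), 5 of 24 in female liver (-0.19 to 0.13), 7 of 25 in male macrophages (-0.23 to 0.56) and 5 of 26 in female macrophages (-0.36 to 0.52). The values below are counts of genes called, given with the count of the edgeR fit first. Why a count moved was not tested, except that refits with fewer libraries have fewer degrees of freedom. Of 368 camera calls 8 passed with an estimated correlation, 366 with DESeq2 size factors and 359 with the replicate block.

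With DESeq2 in male liver the diet in KI went from 0 to 43, KI on the control diet from 606 to 1308 and the interaction from 147 to 711. In female liver the diet in WT went from 7 to 321, the diet in KI from 1176 to 1777, KI on the NASH diet from 12 to 156, KI on the control diet from 1008 to 1595 and the interaction from 635 to 1229. In male macrophages the diet in WT went from 1068 to 1703, KI on the NASH diet from 408 to 840, KI on the control diet from 0 to 4 and the interaction from 0 to 249. In female macrophages the diet in KI went from 297 to 952, KI on the NASH diet from 72 to 554, KI on the control diet from 596 to 1167 and the interaction from 37 to 157. The liver sex difference of the diet effect went from 225 to 504, the averaged KI effect in macrophages from 140 to 400 and the macrophage sex difference of the diet effect from 3 to 265.

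With DESeq2 size factors in edgeR, KI on the NASH diet in female macrophages went from 72 to 21 and the averaged KI effect from 140 to 79 (43 higher and 36 lower, against 58 and 82). With no filter on low counts these 2 went to 0 and 21, the interaction in female macrophages from 37 to 23, KI on the control diet in male liver from 606 to 396, the diet in WT female liver from 7 to 15 and the liver sex difference of the diet effect from 225 to 145. With the replicate number as a block the male liver counts went from 606 to 145 (KI on the control diet) and 147 to 35 (interaction), the female liver counts from 7 to 1 (diet in WT) and 12 to 7 (KI on the NASH diet), the diet in WT male macrophages from 1068 to 1952, and the female macrophage counts from 1652 to 747, 297 to 2, 72 to 6 and 37 to 10 (diet in WT, diet in KI, KI on the NASH diet, interaction). The sex differences of the diet effect went from 225 to 57 in liver and 3 to 1 in macrophages.

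Without the libraries of contradicting sex genes the diet in KI male liver went from 0 to 1, the interaction there from 147 to 626, the diet in WT male macrophages from 1068 to 284, the liver sex difference of the diet effect from 225 to 664 and the averaged KI effect in macrophages from 140 to 40. Both versions of the duplicated library as separate libraries moved KI on the control diet in male liver from 606 to 1307. Its fuller version alone gave 788 there and 2930 for 2730 with the diet in WT, and moved no count by 1.5 times. With the hepatocyte list as a covariate the male macrophage counts went from 3127 to 205 (diet in KI) and 408 to 0 (KI on the NASH diet), and the female ones from 1652 to 98 (diet in WT), 297 to 2 (diet in KI), 72 to 146 (KI on the NASH diet) and 596 to 348 (KI on the control diet). The averaged effect went from 140 to 5 and the sex differences from 3 to 8 (diet) and 584 to 0 (KI). With Lyz2 as a covariate female macrophages went from 1652 to 344 (diet in WT), 297 to 34 (diet in KI), 72 to 0 (KI on the NASH diet) and 37 to 12 (interaction), and the averaged effect from 140 to 16.

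Leaving out each library in turn gave these ranges, in the order diet in WT, diet in KI, KI on the NASH diet, KI on the control diet, interaction. Male liver: 1123 to 3376, 0 to 1, 3799 to 5252, 107 to 835 and 18 to 626. Female liver: 0 to 117, 466 to 1392, 5 to 29, 393 to 1179 and 254 to 1198. Male macrophages: 83 to 1412, 2224 to 3991, 0 to 975, 0 to 1 and 0 to 1. Female macrophages: 768 to 1827, 4 to 688, 0 to 662, 261 to 919 and 5 to 55. The averaged KI effect and the sex differences of the diet and KI effects gave 3237 to 4255, 73 to 664 and 1311 to 2147 in liver, and 5 to 922, 1 to 118 and 385 to 834 in macrophages.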

Other observations

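The gene groups and values given here were picked after the results were seen. Genes of fatty acid synthesis, which hepatocytes also express strongly, rose on the NASH diet in sorted macrophages. In WT males 5 of 19 rose (6 when adjusted over the list alone), in KI males 14 (16), in WT females 10 (12) and in KI females 3 (9). Camera adjusted p were 0.0036, 6.1e-07, 7.2e-07 and 9e-06, but adjusted p = 0.56, 0.22, 0.19 and 0.14 with an estimated correlation. Srebf1, the transcription factor of lipogenesis, rose in each: 215 ± 27.2 against 111 ± 7.17 CPM in WT males (log2 fold change 0.95, adjusted p = 0.0026, n = 5 and 4), 210 ± 39.4 against 112 ± 4.4 CPM in KI males (0.91, adjusted p = 0.00047, n = 5 and 4), 209 ± 23.4 against 120 ± 13.4 CPM in WT females (0.80, adjusted p = 0.00077, n = 6 and 4) and 175 ± 25 against 126 ± 15.7 CPM in KI females (0.47, adjusted p = 0.039, n = 6 and 4). The call in KI females was lost in 8 of 20 refits with a library left out, the others in none. The hepatocyte list had 1 of 18 members lower and none higher in WT males, but 15 higher in KI males, 9 in WT females and 6 in KI females. With that list as a covariate Srebf1 was at 0.94, 0.98, 0.74 and 0.41 in the same order (adjusted p = 0.0036, 0.027, 0.027 and 0.68), and 6, 2, 1 and 0 fatty acid synthesis genes rose (median 0.54, 0.73, 0.30 and 0.15, against 0.38, 1.04, 0.94 and 0.48 without it).

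The cystine transporter Slc7a11, an NRF2 target, was low in macrophages on the control diet and higher on the NASH diet, at 10.8 ± 8.65 against 0.058 ± 0.067 CPM in KI males (adjusted p = 0.0012) and 1.96 ± 0.869 against 0.0146 ± 0.0292 CPM in WT females (adjusted p = 0.0013), 2.18 ± 2.2 against 0.207 ± 0.0758 CPM in KI females (adjusted p = 0.030), and without passing at 2 ± 2.19 against 0.221 ± 0.0464 CPM in WT males (adjusted p = 0.067). Il6 fell in WT males (-1.92, adjusted p = 0.042; 31.4 ± 13.8 against 119 ± 69.8 CPM).

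Further values describe the tables. The Spearman correlation of fold change with exonic length was 0.34 for KI against WT in male liver on either diet and -0.34 for the liver sex difference of the KI effect, and no other comparison passed 0.26. Across genes the KI effect on the NASH diet in male and in female macrophages, from different animals, had a Pearson correlation of -0.23 and a Spearman correlation of 0.19, which differ in sign.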
